A study of Mus musculus with 5 samples.

How the data were processed

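Expression was measured on 5 Affymetrix mouse arrays, 3 of uninfected and 2 of infected dendritic cells, with amplified RNA labelled in 2 cycles per the labels' protocols. The authors deposited log2 values made with GCRMA, per the submitters' processing notes, in which no version is given. The values were used on that log2 scale as deposited, and the scanner files were not used here. Their floor of 2.24 on every array holds probe sets without signal, so values there have no order.

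Probe sets were named from the platform's annotation table, which gave 1 gene to 34958 probe sets, several to 932 and none to 9211. Symbols were looked up by Entrez number in a table of mouse genes on GRCm38.p6, which matched 34754 of the probe sets with 1 gene and changed 0 symbols. A probe set with several genes named none, and the 64 control probe sets were left out of all tests. A probe set entered the tests if its value exceeded log2 4 on at least 2 of the 5 arrays. Each gene was read from its tested probe set with the highest mean over the 5 arrays.

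Each probe set was fitted with limma 3.58.1 in R 4.3.3, using lmFit on the group and eBayes with a mean-variance trend, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 3 residual degrees of freedom and a prior of 2.09. Gene lists were tested with camera at a preset correlation of 0.01 between genes, for lists with at least 3 measured genes, with camera at an estimated correlation, camera on ranks and the directional test of fry as alternatives. The 30 functional lists covered sterol and lipid metabolism, energy metabolism, antigen presentation, inflammation, phagocytosis, lysosomes, stress, iron, cell death, cell cycle and matrix, and 10 lists held markers of cell types. They named 696 genes, of which 526 were measured, and the others were not analysed here. Each list was also tested member by member with p adjusted over the list alone, which leaves the number of lists uncorrected.

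The genes to be named were set by a rule before the data were examined. It took the 8 largest increases and 8 largest decreases among genes past the threshold in which no infected array overlapped an uninfected one and both group means exceeded log2 4. It added 3 and 3 genes with 1 group mean at or below that level, up to 4 changed genes per list or otherwise the 2 brightest members, and H2-Aa, H2-Ab1, H2-Eb1 and Cd74. As no gene passed, only the brightest list members and these 4 genes were named by it; genes past the threshold over their list alone, and a few others, were chosen after their values were seen. The rule was then applied to the fit with centred arrays and the replicate number as a block.

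Replicates 1 and 2 occur in both groups, but no label says what the number marks, so the planned fit had no block. Batches were looked for in the 24 poly-A control probe sets. Differences within a number were taken after centring each array on the median of the tested probe sets. RNA integrity was read from the 3 prime minus 5 prime difference of the Actb and Gapdh control probe sets and compared with an exact permutation test. Alternatives covered the filter, the prior, the scaling, array weights, the replicate block, the choice of probe sets and leaving out each array. The steps were tested on simulated arrays with the spread of the real ones and their correlation within a replicate number. There were 5 runs with 200 changed probe sets each among 17291. Probe sets were drawn independently of each other, unlike real genes, so the false calls counted need not hold for the real arrays. The planned fit found 3.6% of changes of log2 1 and 65.8% of changes of log2 2, with a mean of 0.2 false calls per run. Centring with a fixed block found 12.4% and 92.2%, with 8 false calls per run.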

Results

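Dendritic cells grown from BALB/c mouse bone marrow were profiled on mouse expression arrays with and without amastigotes of Leishmania amazonensis, the form of the parasite that lives inside host cells. Parasites were added on day 14 of culture at 4 per cell, and cells were kept at 34 °C for 24 h. Cells were then sorted by surface MHC class II, and infected cells also by the red fluorescent protein that the parasites carry. There were 3 arrays of uninfected and 2 of infected cells. Each array gave a GCRMA log2 value for 45101 probe sets, from a floor of 2.24 to a highest value between 16.03 and 16.17, and between 37.1% and 38.0% of the probe sets other than controls lay above log2 4. The number of arrays limits the precision. The tests covered 17291 probe sets, which stood for 9350 genes. All differences are log2 values, infected minus uninfected.

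The comparison asks how the transcripts of dendritic cells that hold amastigotes differ from those of cells cultured without them. Genes of the vacuolar ATPase, the proton pump that acidifies lysosomes, were higher in infected cells in camera with a preset correlation. So were lists of lysosomal genes, cholesterol uptake genes, a joint list of efflux genes and LXR targets, maturation genes and chemokine genes. With an estimated correlation each of these lists had an adjusted p of 0.778, and in fry an adjusted p of at least 0.363. Atp6v0d2, a subunit of that pump, was 2.67-fold higher, and Ch25h, the cholesterol 25-hydroxylase, was 3.94-fold higher. Ciita, the master regulator of MHC class II transcription, was 2.12-fold lower and H2-Ob, which restrains peptide loading, was 2.59-fold lower. The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 themselves differed by 0.12, -0.08 and 0.12. H2-Ab1 ran from -0.57 to 0.12 over the alternatives of the fit. The cells were sorted by surface MHC class II, so these values hold only for cells selected on that protein.

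Over all genes tested, no gene passed: limma took 0 of 17291 probe sets and 0 of 9350 genes past an adjusted p of 0.05, with 2442 probe sets at an unadjusted p under 0.05 against 865 expected by chance. Grouping uninfected replicate 1 with infected replicate 1, against the other 3 arrays, gave 2980 such probe sets, a grouping that follows the replicate number. A fit chosen after the data were examined centred the arrays and took that number as a block. In it 3823 probe sets had an unadjusted p under 0.05 in limma. Exchanging the labels within replicate 1 gave 107, but the exchange only swaps the group difference of that fit with its residual. The 107 is therefore not a separate control. The lowest adjusted p of the planned fit in limma was 0.0888. The other planned fits gave 0 probe sets, except 13 without the filter on level and 9 with each array centred on its median. Both infected arrays lay above all uninfected arrays for 950 genes and below them for 2338, together 35.2% of the genes where chance gives 20%. With each array centred on its median the counts were 1994 above and 1217 below, so the balance of directions depends on the scaling. The median difference of all genes was -0.15, so the shift of each list is given relative to it. Differences of single genes in the planned fit, and counts of genes that rose or fell in it, are as deposited, without that offset. Of the 30 functional lists and 10 marker lists fixed before the data were examined, 35 had at least 3 measured genes, and camera took 13 past an adjusted p of 0.05, 12 higher and 1 lower. Other splits of the same arrays gave up to 18 lists, with uninfected replicates 1 and 2 against the rest. That split keeps both infected arrays in 1 group, so it holds part of the infection contrast. Splits that place the infected arrays in different groups gave 3 to 16 lists. The 16 came with uninfected replicate 3 and infected replicate 2 against the rest, so the number of lists does not stand out from regrouped arrays. The count of lists was 6 without infected replicate 2, and with an estimated correlation between genes it was 0.

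Poly-A control transcripts, which are added to the RNA before labelling, placed infected replicate 1 nearest to uninfected replicate 1 and infected replicate 2 nearest to uninfected replicate 2. Their root mean square log2 difference was 0.47 and 0.19 within these numbers and between 0.72 and 2.33 for all other pairs of arrays. List shifts are therefore also given within replicate 1 and within replicate 2, after centring each array on its median. Uninfected replicate 3 shares its number with no infected array.

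**Figure D1:**
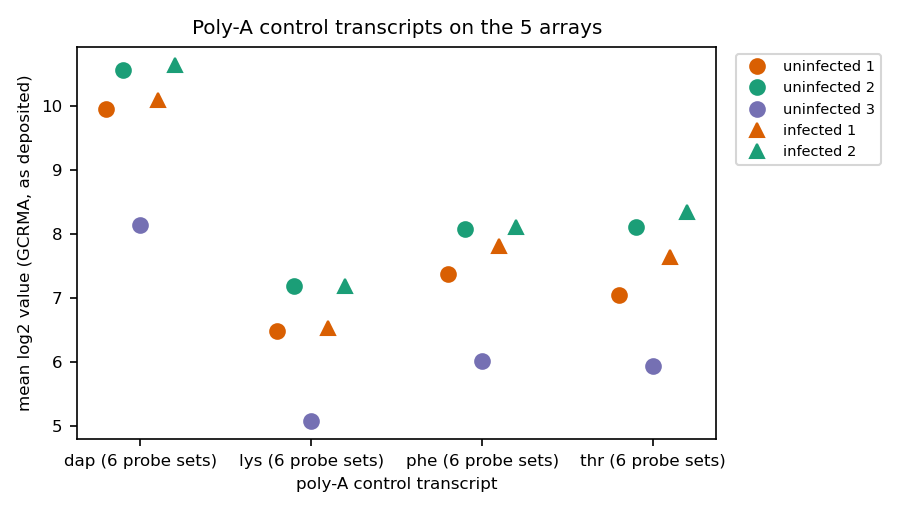
Mean log2 value of the probe sets of each poly-A control transcript (y axis) on each array, with circles for uninfected and triangles for infected cells and one colour per replicate number. The dap value was 9.96 on uninfected replicate 1 and 10.10 on infected replicate 1, 10.57 and 10.65 on the replicate 2 arrays, and 8.14 on uninfected replicate 3.

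The vacuolar ATPase list had the lowest p of all lists. All 15 measured members lay above the median difference of all genes, and 13 were higher on both infected arrays than on every uninfected array. Adjusted over the list alone, 10 of the 15 rose and none fell, each with an adjusted p of 0.0435 in limma. Atp6v0d2 measured 10.67 ± 0.74 (SD, n = 3) in uninfected and 12.09 ± 0.43 (SD, n = 2) in infected cells. Atp6v1a measured 10.87 ± 0.17 and 11.88 ± 0.42, and Atp6v1c1 12.43 ± 0.21 and 13.38 ± 0.25. The list's median lay 0.66 above that of all genes, 0.95 within replicate 1 and 0.52 within replicate 2 (camera adjusted p = 2.11e-11). With an estimated correlation its adjusted p was 0.778. Adjusted over the list alone, 0 members passed without any 1 of the 3 uninfected replicates or without infected replicate 1, and 5 without infected replicate 2.

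Lysosomal hydrolases and membrane proteins were higher as a list, by a median of 0.41 over 24 genes, with 0.54 within replicate 1 and 0.46 within replicate 2 (camera adjusted p = 0.000114). No member passed by itself, also when adjusted over the list alone, and 9 were higher on both infected arrays than on every uninfected array. Ctsk, a cysteine protease, measured 7.18 ± 0.75 in uninfected and 9.31 ± 0.96 in infected cells, and the aspartic protease Ctsd differed by 0.93, or 0.59 without uninfected replicate 1. Autophagy genes shifted by 0.25 over 16 genes (0.27 within replicate 1 and 0.31 within replicate 2, camera adjusted p = 0.0277), and 0 passed over the list alone. Map1lc3b and Sqstm1, which mark autophagosomes and their cargo, differed by 0.31 and 0.58, and the former by 0.11 without infected replicate 1. Oxidative stress genes shifted by 0.30 over 19 genes (0.66 and 0.20, camera adjusted p = 0.00348), with 0 past the threshold over the list alone. The cystine transporter Slc7a11 differed by 1.29, the metallothionein Mt2 by 1.19 (0.75 without uninfected replicate 1) and the lipid peroxide reductase Gpx4 by 0.74. With an estimated correlation the adjusted p was 0.778 for each of these lists. Without infected replicate 2 the adjusted p was 0.0652 for the lysosomal list and 0.232 for autophagy, autophagy had 0.105 without uninfected replicate 1, and oxidative stress had 0.253 without infected replicate 1. In the same order the medians of autophagy were then 0.04 and 0.04 and that of oxidative stress 0.04, and the latter was 0.54 without infected replicate 2. Autophagy also failed without the filter on level (adjusted p = 0.138) and with array weights (adjusted p = 0.0619).

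Genes that take up and move cholesterol were higher, by a median of 0.43 over 14 genes, with 0.49 within replicate 1 and 0.52 within replicate 2 (camera adjusted p = 0.00184). Adjusted over the list alone, 3 members rose and none fell, namely Olr1, a receptor for oxidised lipoprotein, by 1.73, and Npc1 and Npc2, which export cholesterol from lysosomes, by 1.00 and 0.39. Efflux genes and targets of the LXR receptors shifted by 0.55 over 11 genes, with 0.62 and 0.61 within the replicate numbers (camera adjusted p = 0.00377). Within that joint list, the hydroxylase gene Ch25h and Mylip rose by 1.98 and 0.87 when adjusted over the list alone, and none fell. Ch25h measured 7.85 ± 0.33 in uninfected and 9.82 ± 0.17 in infected cells. Sterol synthesis genes shifted by 0.28 over 20 genes (camera adjusted p = 0.0481), with 0.15 within replicate 1 and -0.13 within replicate 2, and 0 members passed over the list alone. Its brightest members Hmgcs1 and Idi1, both enzymes of the mevalonate pathway, differed by -0.27 and 0.19. Without uninfected replicate 3 both were below 0, at -0.56 and -0.11, Idi1 also turned negative with the replicate number as a block alone or after quantile normalization or cyclic loess, and Hmgcs1 had -0.09 without infected replicate 2. With an estimated correlation the adjusted p was 0.778 for each of the 3 lists. Without infected replicate 2 the adjusted p was 0.0652 for efflux and 0.0652 for synthesis, and synthesis also had 0.253 without infected replicate 1, 0.728 without uninfected replicate 3 and 0.826 with the replicate number as a block. The synthesis list failed too without the filter, with array weights, without _x_at and _s_at probe sets and under all 3 other scalings, with adjusted p between 0.0692 and 0.254. Its median ran from 0.10 without uninfected replicate 3 to 0.43 without uninfected replicate 2, and that of the efflux list was 0.31 without uninfected replicate 1.

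Costimulation and dendritic cell maturation genes were higher by a median of 0.62 over 22 genes, with 0.30 within replicate 1 and 0.78 within replicate 2 (camera adjusted p = 9.52e-05). Ccr7, the receptor that guides dendritic cells to lymph nodes, rose by 1.38 and Cd200, an inhibitory ligand, rose by 1.96 when adjusted over the list alone, and none fell. Cd83 and Pdcd1lg2 differed by 1.11 and 1.14 and did not pass, and Pdcd1lg2 had 0.68 without infected replicate 1. Chemokines and their receptors shifted by 0.29 over 21 genes, with 0.64 and 0.81 within the replicate numbers (camera adjusted p = 0.00348). In that list, adjusted over the list alone, Cxcr4, Ccr7 and Ccl6 rose by 2.45, 1.38 and 0.71 and Ccl12, a ligand of Ccr2, fell by 3.41. Ccl12 was at least 8.91-fold lower against a level of log2 4. Genes of NF-kB feedback shifted by 0.34 over 16 genes (0.18 and 0.71, camera adjusted p = 0.0228), with 0 past the threshold over the list alone. Nfkbia, the inhibitor of NF-kB, differed by -0.07 and turned positive with arrays centred on their medians and without uninfected replicate 1 (0.09), and Tnfaip2 differed by -0.45. With an estimated correlation the adjusted p was 0.778 for each of these lists. Without infected replicate 2 the adjusted p was 0.0616 for chemokines, and for NF-kB it was 0.375 without infected replicate 1 and 0.269 without uninfected replicate 2. Without uninfected replicate 2 the medians of the maturation, chemokine and NF-kB lists were 0.32, 0.17 and 0.10, without infected replicate 2 they were 0.86, 0.84 and 0.71, without uninfected replicate 1 they were 0.81, 0.59 and 0.63, and for NF-kB the median was 0.09 without infected replicate 1; the chemokine median was 0.56 without uninfected replicate 3. Without the filter on level the adjusted p was 0.138 for both chemokines and NF-kB, and NF-kB had 0.0937, 0.0551 and 0.0533 under quantile normalization, median centring and cyclic loess.

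Arginine and polyamine genes shifted by 0.25 over 12 genes (0.29 within replicate 1 and 0.19 within replicate 2, camera adjusted p = 0.0339). Arg2, the mitochondrial arginase, rose by 2.30 when adjusted over the list alone and none fell, while the arginine transporter Slc7a2 differed by 2.58 without passing. Matrix proteases and their inhibitors shifted by 0.51 over 12 genes (0.92 and 0.52, camera adjusted p = 0.0339), with 0 past the threshold over the list alone and differences of 1.36 for Mmp14 and 0.91 for Serpinb2. Cell cycle genes were lower by a median of -0.52 over 26 genes, with -0.95 within replicate 1 and -0.35 within replicate 2 (camera adjusted p = 0.0481), and 0 passed over the list alone. Ccnd1 and Ccnd2, the D-type cyclins that drive entry into the cycle, differed by -1.44 and -0.80, and Ccnd2 by -0.02 without uninfected replicate 1, -0.37 without infected replicate 2 and -1.23 without infected replicate 1. With an estimated correlation the adjusted p was 0.778 for the first pair of lists and 0.826 for the cell cycle. Without infected replicate 1 the adjusted p was 0.0623 for arginine genes and 0.704 for the cell cycle, whose median was then 0.21. Without infected replicate 2 it was 0.168 for arginine genes and 0.294 for matrix proteases, without uninfected replicate 1 it was 0.476 for matrix proteases and 0.103 for the cell cycle, and without uninfected replicate 2 it was 0.361 for the cell cycle. The matrix median was 0.09 without uninfected replicate 1, 0.21 without infected replicate 2, 0.79 without infected replicate 1 and 0.85 without uninfected replicate 3, and the cell cycle median was -0.32 without uninfected replicate 2 and -1.12 without infected replicate 2. Matrix proteases also failed without the filter, with array weights and under quantile normalization, median centring and cyclic loess, with adjusted p between 0.0802 and 0.244. Arginine genes failed without the filter, under quantile normalization, cyclic loess and on ranks, with adjusted p between 0.0533 and 0.101.

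Within the MHC class II presentation list, adjusted over the list alone, 5 of 13 measured genes fell, 1 rose and 7 did not pass. H2-Ob measured 11.90 ± 0.06 in uninfected and 10.53 ± 0.31 in infected cells (list-alone adjusted p = 0.00605, limma), and Ciita 9.91 ± 0.15 and 8.83 ± 0.05 (list-alone adjusted p = 0.00719, limma). H2-Oa, the partner of H2-Ob, fell by 1.12, H2-DMb2, part of the peptide loading factor, by 0.92, and Marchf1, a ligase that removes MHC class II from the surface, by 0.89. The cathepsin Ctss rose by 0.30. Over the alternatives of the fit H2-Ab1 ran from -0.57 to 0.12. The invariant chain gene Cd74 differed by -0.11, and its sign and that of H2-Ab1 turned with arrays centred on their medians and without infected replicate 1. Without that array H2-DMb2 and Marchf1 differed by -0.59 and -0.55. As a list these genes did not pass: the median was 0.05, 0.00 within replicate 1 and 0.06 within replicate 2, whereas the mean was -0.23 and camera placed the list lower with an adjusted p of 0.403. With quantile normalization the list passed as lower (camera adjusted p = 0.0406), and over all alternatives its median ran from -0.56 to 0.07 and its adjusted p from 0.0406 to 0.826. Without any 1 of the 3 uninfected replicates or infected replicate 1, 2 genes passed over the list alone, and both fell.

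**Figure D2:**
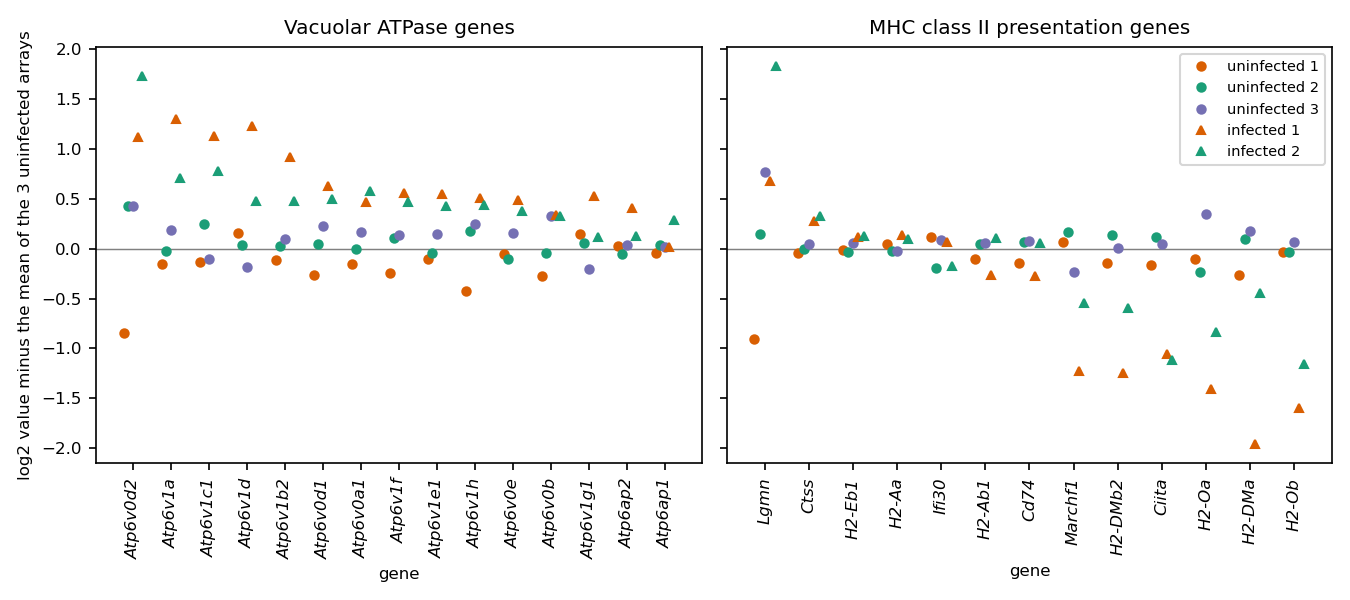
Log2 value minus the mean of the 3 uninfected arrays (y axis) for the measured genes of the vacuolar ATPase list (left) and the MHC class II presentation list (right), with circles for uninfected and triangles for infected arrays and one colour per replicate number. Atp6v1a differed by 1.00 and H2-Ob by -1.37, while H2-Aa differed by 0.12.

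Lists that did not pass had these medians over all genes, with the camera adjusted p. Inflammatory cytokines and mediators shifted by 0.78 (0.0582), and their member Inhba, a subunit of activin A, rose by 3.89 when adjusted over the list alone. Iron handling shifted by 0.32 (0.202), and adjusted over the list alone Tfrc, the transferrin receptor, fell by 1.26 and Ncoa4, the receptor for ferritin breakdown, rose by 0.81. With the replicate number as a block the camera adjusted p was 0.0247 for the inflammatory list and 0.0407 for iron handling, with arrays also centred 0.0688 and 0.0885, and with an estimated correlation in that fit 0.702 for both. Without uninfected replicate 3 it was 0.0168 for the inflammatory list and 0.0352 for iron handling, and without infected replicate 1 it was 0.00311 for the inflammatory list, 0.00409 for glycolysis and 0.00771 for the NADPH oxidase. Without infected replicate 2 the adjusted p was 0.655 for the inflammatory list, 0.520 for iron handling and 0.961 for both glycolysis and the NADPH oxidase. Leaving out 1 array, the median ran from 0.20 to 1.23 for the inflammatory list and from -0.06 to 0.47 for glycolysis, in both from without infected replicate 2 to without infected replicate 1, as it did from 0.18 to 0.60 for the NADPH oxidase. For iron handling it ran from 0.11 without uninfected replicate 1 to 0.57 without uninfected replicate 3, and was 0.19 without uninfected replicate 2. In the list of fatty acid synthesis, desaturation and activation the median was -0.02 and the mean 0.24 (0.566), and over the list alone the fatty acid binding proteins Fabp4 and Fabp5 rose by 2.37 and 0.78 and the elongase Elovl6 fell by 1.26. Leaving out 1 array, that median ran from -0.26 without infected replicate 1 to 0.10 without infected replicate 2. Neutral lipid storage shifted by 0.08 (0.566) with Plin2 at 0.65 (0.39 without infected replicate 2), fatty acid oxidation by 0.03 (0.783), glycolysis by 0.25 (0.188) and oxidative phosphorylation by 0.07 (0.859). The median was 0.16 for MHC class I presentation (0.274), -0.03 for the type I interferon response (0.859), 0.02 for alternative activation (0.527) and 0.32 for pattern recognition (0.188). For alternative activation it ran from -0.16 without uninfected replicate 2 to 0.41 without uninfected replicate 3. With all arrays the median was -0.02 for phagocytic, Fc and complement receptors (0.928), 0.35 for the NADPH oxidase (0.202), 0.12 for the unfolded protein response (0.566), 0.22 for heat shock proteins (0.188) and 0.22 for apoptosis regulators (0.268). For the phagocytic receptors it was -0.44 without infected replicate 2 and 0.24 without infected replicate 1. The interferon and phagocytic receptor lists had a median below 0 while camera placed them higher.

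Markers of other cells were read in the same way. Conventional dendritic cell markers had a median of -0.07 (camera adjusted p = 0.810), and over the list alone Ccr7 and Irf8 rose by 1.38 and 0.71 and H2-DMb2 and Dpp4 fell by 0.92 and 1.13. Plasmacytoid markers had a median of -0.43 (0.386), with Pacsin1 lower by a difference of -1.72. Their median was -0.03 without uninfected replicate 3, -0.05 without infected replicate 2 and -0.89 without uninfected replicate 2. Macrophage markers had a median of -0.33 (0.566), with -0.37 within replicate 1 and 0.15 within replicate 2, and their median ran from -0.79 without infected replicate 2 to 0.12 without infected replicate 1. Among them the complement genes C1qa, C1qb and C1qc differed by -1.18, -1.11 and -1.50 and Mertk and Mrc1, both receptors for uptake, by 0.95 and 0.62. Without infected replicate 1 the complement genes differed by -0.66, -0.69 and -0.41 and Mrc1 by 1.18, without infected replicate 2 C1qc differed by -2.60 and Mrc1 by 0.07, and without uninfected replicate 1 Mertk and Mrc1 differed by 0.31 and 0.14, while Mertk had 1.46 without uninfected replicate 3. Neutrophil markers had a median of 0.91 (0.0862), with 0.31 within replicate 1 and 1.56 within replicate 2 and keratinocyte and fibroblast markers one of 0.29 (0.287). The neutrophil median was -0.13 without infected replicate 2, 0.45 without uninfected replicate 1 and 1.41 without infected replicate 1. That list passed in camera with the replicate number as a block (adjusted p = 0.00252), without uninfected replicate 3 (0.0168) and without infected replicate 1 (0.000194), and had an adjusted p of 0.961 without infected replicate 2 and 0.778 with an estimated correlation, or 0.702 with arrays centred and the block. Infected replicate 2 had Ngp at 8.64, a granule gene of neutrophils, against 5.12 to 6.11 on the other arrays. Without that array the medians of the lysosomal, efflux and chemokine lists were 0.30, 0.44 and 0.84. Within replicate 1, which does not use it, these lists shifted by 0.54, 0.62 and 0.64. The mast cell, eosinophil, B cell, erythroid and T and NK cell lists had fewer than 3 measured genes and were not tested. Siglecf lay at 11.15 on infected replicate 2 and between 7.40 and 9.20 elsewhere, and no T or NK cell marker exceeded 3.62 on any array. Among the single measured genes, Car2 differed by 1.65, with 0.59 without infected replicate 1, 1.01 without uninfected replicate 2 and 2.70 without infected replicate 2. Ighm differed by -1.40 because of infected replicate 1, where it lay at 4.91 against 7.64 to 7.94 on the other arrays, and by 0.06 without that array. The mast cell genes Gata2 and Hdc differed by -0.03 and -0.35, with 0.79 for Gata2 without infected replicate 1 and -0.86 without infected replicate 2, and -0.10 for Hdc without uninfected replicate 2. The mast cell protease gene Cpa3, which exceeded log2 4 on 1 array and was not tested, lay at 6.52 on infected replicate 2 and between 2.24 and 2.76 elsewhere.

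**Figure D3:**
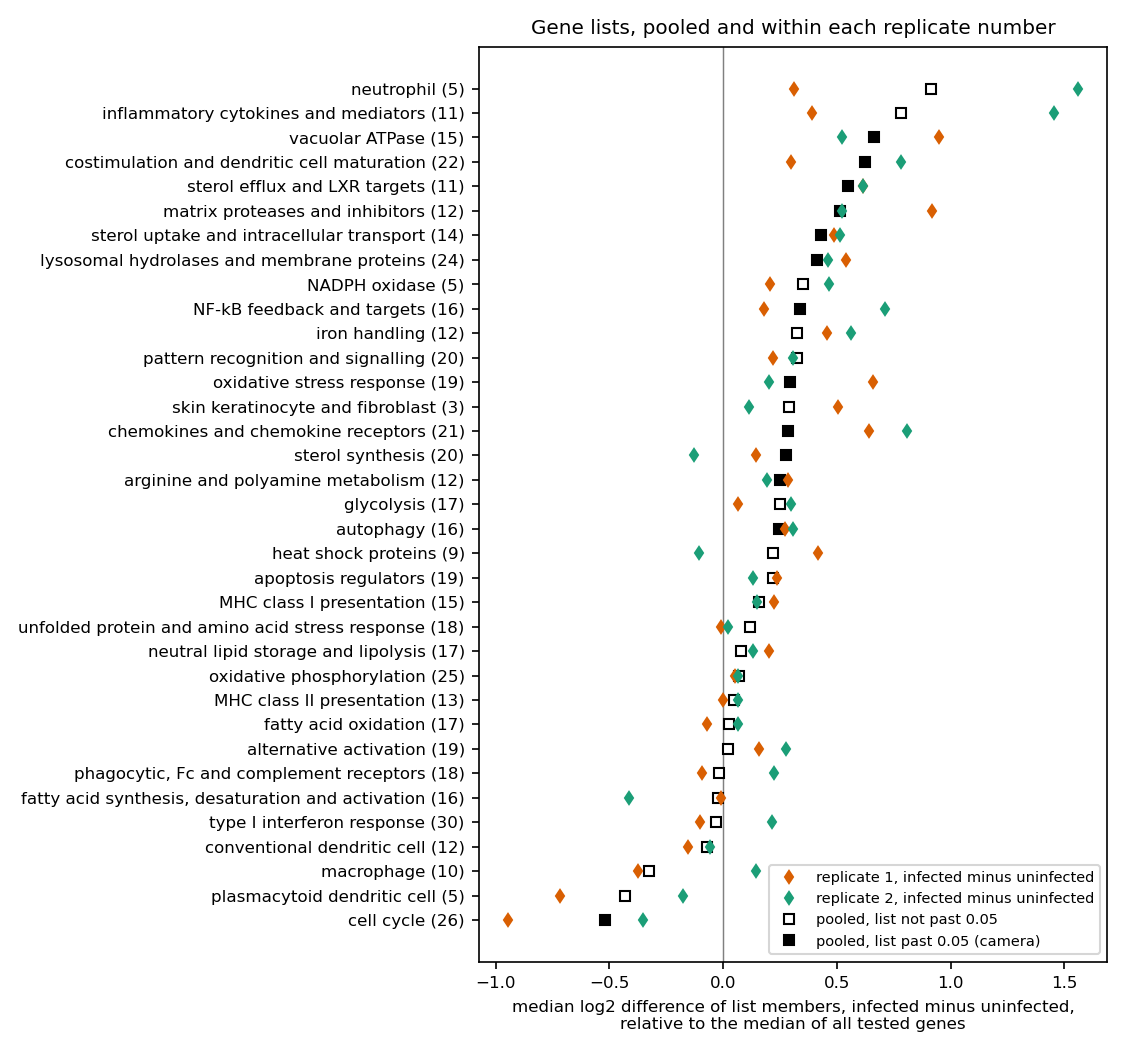
Median log2 difference of each list's measured genes relative to all tested genes (x axis) for the 35 tested lists (y axis, number of genes in brackets), with squares for the pooled value, filled where camera's adjusted p is under 0.05, and diamonds for the difference within replicate 1 and within replicate 2. The vacuolar ATPase list lay at 0.66 and the cell cycle list at -0.52.

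The 3 prime minus 5 prime difference of control probe sets, a sign of RNA integrity, did not separate the groups. For Actb it was 1.49 ± 0.46 in infected and 1.34 ± 0.37 in uninfected cells, a difference of 0.16 with an exact two-sided permutation p of 0.5, and for Gapdh the difference was -0.04 with an exact permutation p of 0.7. The 10 splits of 5 arrays allow no p under 0.1. Within a replicate number the uninfected and infected arrays lay close. Actb had 1.77 and 1.82 in replicate 1 and 1.14 and 1.17 in replicate 2, and Gapdh 2.06 and 2.01 and then 1.54 and 1.52. The spread within each group therefore went partly with the replicate number, which the permutation test ignores.

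A further fit, chosen after the data were examined, centred each array on its median and took the replicate number as a block, and the genes named from it follow the rule set for the planned fit. In it 624 probe sets passed, 408 higher and 216 lower in infected cells, which stand for 400 genes, 363 of them at least 2-fold. Its largest increases among genes above log2 4 in both groups were Gng4, a G protein subunit, by 4.24, Bex1 by 3.97, Rragd, a Rag GTPase that signals at the lysosome, by 3.89, Inhba by 3.89 and Jcad by 3.47. Plpp3, a lipid phosphatase, Tent5c, a poly(A) polymerase, and Fabp4 followed with 3.27, 3.09 and 3.06. Its largest decreases were Ctnnd2, Septin3, the pseudokinase Trib2, Kbtbd11 and the transcription factor Mef2c, with differences of -3.38, -3.18, -2.80, -2.62 and -2.48, and then Ppp1r14a, Klrb1b and the inhibitory receptor Cd72 with -2.45, -2.43 and -2.39. For genes chosen by this fit that lay at or below log2 4 in one group, sizes come from the group means as deposited, not from the fit. Tnfrsf11b, the decoy receptor for RANKL, was at least 10.5-fold higher, Calhm6 at least 8.97-fold higher and a probe set of Rps16 at least 4.24-fold higher. Ccl12, Srgap3 and Heg1 were at least 8.91-fold, 5.89-fold and 1.66-fold lower. In the same fit 14 of 15 vacuolar ATPase genes and 15 of 24 lysosomal genes passed as higher when adjusted over the list alone, as did Slc7a2, Arg2 and Sat1 among the arginine and polyamine genes. So did 9 of 22 maturation genes, 8 of 12 matrix genes, 7 of 19 oxidative stress genes, 7 of 14 sterol uptake genes, 6 of 11 efflux genes, 5 of 16 NF-kB genes and 3 of 16 autophagy genes. Of the chemokine list 9 genes passed as higher and 1 as lower, of the MHC class II list 3 as higher and 6 as lower, of the cell cycle list 3 as lower, and of the sterol synthesis list 0. Of all 9350 genes in this fit, 2208 had an unadjusted p under 0.05 in limma. Both infected arrays lay above all uninfected arrays for 1994 of the 9350 genes and below them for 1217. The list counts were not tested against these shares. The adjusted p in limma was 0.0161 for Rragd, Plpp3 and Tent5c and 0.0165 for Trib2. In the planned fit Jcad, Cd72, Calhm6 and Tnfrsf11b differed by 3.42, -2.27, 3.47 and 4.20, and without infected replicate 1 by 1.74, -1.36, 2.21 and 2.77. The fit with centring and the block leaves 1 residual degree of freedom. With quantile normalization or cyclic loess in place of centring the same block took 0 probe sets past the threshold in limma, with 3543 and 3533 at an unadjusted p under 0.05. The 624 probe sets had a median difference, in their direction with centring, of 1.55 with centring, 1.54 with quantile normalization and 1.56 with cyclic loess, and median standard errors of 0.23, 0.21 and 0.22. The prior degrees of freedom were 5.12, 3.26 and 3.20, and with those of centring 1080 and 1042 probe sets passed under the other scalings. Of 174 genes chosen by rule or as stated, 138 kept 1 direction in every alternative of the fit in which they were tested. Most were tested in all 24, and some in fewer, such as Heg1 in 21. Of the 174, 34 turned without some 1 array, and 96 turned or moved by over 1.5 times.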

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

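The test of batches, both tests of scaling, the test of macrophage markers and the test of neutrophil markers were chosen after their results were seen. Hybridisation control probe sets named cre, which report on staining rather than on the cells, were higher on both infected arrays than on all uninfected arrays, by a mean of 0.53, a signal outside the main measurement. Chance gives such an order upward for 1 in 10 control families. The other hybridisation families biob, bioc and biod had infected means higher by 0.73, 0.57 and 0.58 without full separation of the groups. The transrec control probe sets, which read the transferrin receptor transcript, were lower on both infected arrays than on all uninfected arrays, by a mean difference of -1.78.

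Many probe sets pass once arrays are centred and the replicate number is taken as a block. The arrays of one number may share a labelling batch, since the largest poly-A control distance within a number was 0.659 of the smallest distance between other arrays. With the same block at most 0 probe sets passed in limma under quantile normalization or cyclic loess, with 3543 and 3533 at an unadjusted p under 0.05, against 624 and 3823 with centring. The lowest median difference of these 624 under the other scalings was 1.54, against 1.55 with centring. Its standard error of 0.03 is over probe sets, which are not independent replicates. These probe sets were chosen by their differences with centring, and the medians of the arrays lay only between 7.61 and 7.97. A large fall could therefore hardly occur, so the values show only that the sizes changed little. The median standard error of the 624 was 0.21 and 0.22 against 0.23. The calls ended because the prior degrees of freedom were 3.26 and 3.20 against 5.12. With 5.12 the other scalings gave 1080 and 1042 probe sets, so the number that passes rests on that estimate. Exchanging the labels within replicate 1 gave 0 probe sets, so 1 of the 2 arrangements reached the real count. The exchange only swaps the group difference of that fit with its residual, so it is not a separate test. So few arrangements also cannot give a share under 0.05. A shared culture day, and infection itself, stay open.

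Vacuolar ATPase genes were higher in infected cells by a median of 0.66 over all genes. In camera with an estimated correlation the list had an adjusted p of 0.778, and in fry one of 0.363. With the 3 prime minus 5 prime difference as a covariate the list's median was 0.67, with a standard error of 0.08 over its genes. Between the groups that difference itself differed by only 0.16 for Actb and -0.04 for Gapdh, within the spread of the arrays. The covariate could therefore hardly move the list's median, so this test cannot decide on RNA integrity. Uninfected and infected arrays of one number were nearly alike in it. For Actb it was 1.77 and 1.82 in replicate 1, and 1.14 and 1.17 in replicate 2. For Gapdh it was 2.06 and 2.01, and 1.54 and 1.52. Between these same arrays the list still shifted by 0.95 and 0.52. These values argue against RNA integrity, as these controls read it, for replicates 1 and 2. The median of the macrophage markers was -0.33, below the list's median by more than 2 standard errors of 0.41, but the gap was 0.42 without infected replicate 1 and 0.82 without uninfected replicate 3, within 2 standard errors, so a larger share of macrophages stays open. Among the 10 splits of the 5 arrays, 1 reached the real value in size, and 10 splits are too few for a share under 0.05. The next in size was -0.53, with uninfected replicates 1 and 2 against the rest (camera adjusted p = 2.41e-08). That split keeps both infected arrays in the other group, so it holds part of the same contrast. Splits that place the infected arrays in different groups ran from -0.10 to 0.30, the highest positive value besides the real one. Infection and unlike culture stay open as possible explanations.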

How the results depend on the processing

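All named settings with a random block, the fixed block joined to a scaling or a filter, and the covariate were chosen after the data were examined. Of the probe set counts, 0 in the planned fit, the alternatives gave 13 without a filter, 9 with median centring, 624 with centring and a fixed replicate block, 1087 with centring and a random replicate block, 389 with a random replicate block alone, and 333 with centring, a fixed block and a filter at log2 5. Genes numbered 10, 4, 400, 652, 217 and 224 in that order, and genes changed at least 2-fold 3, 4, 363, 412, 175 and 212. The share of higher probe sets was 59.3% with centring and a random block and 30.8% without centring. The fixed replicate block alone gave 0 probe sets and 0 genes, with 3553 probe sets at an unadjusted p under 0.05, and the deviations of arrays with the same number correlated at 0.58 across genes, which are not independent replicates. All other settings gave 0, also without any 1 array. Lists past the threshold numbered 13, and 7 without a filter, 0 with an estimated correlation, 0 with fry, 15 with the fixed replicate block, and 6 to 15 without 1 array. Lists under a random block were not run. The cell cycle median ran from -1.12 without infected replicate 2 to 0.21 without infected replicate 1, where it turned. The cause of these changes was not tested. Of 13 lists past the threshold, 3 (vacuolar ATPase, sterol uptake and costimulation) stayed past it in all 17 other fits set before the data were examined. Signal near the floor limits what dim probe sets show.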

Other observations

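The test of granulocyte markers was chosen after its result was seen. Several granulocyte and mast cell transcripts were higher on infected replicate 2 than on the other arrays. Ngp lay at 8.64 there against 5.12 to 6.11 elsewhere, S100a9 at 6.37 against at most 4.38, and Siglecf, a lectin of eosinophils and alveolar macrophages, at 11.15 against at most 9.20. S100a8 and Mmp8 were higher there by less, at 9.17 and 11.11 against at most 9.15 and 10.75. The mast cell and basophil genes Cpa3, Fcer1a and Ms4a2 lay at 6.52, 3.71 and 3.69 there and at most at 2.76, 2.24 and 2.29 elsewhere. Gata2 lay at 7.91 there and at most at 7.34 elsewhere. Other markers of these cells did not follow. Hdc and the eosinophil gene Prg2 lay at 5.04 and 2.31 there, against up to 5.85 and 3.76 elsewhere. Mcpt4, Mcpt8, Tpsb2, Cma1, Epx, Il5ra and Ccr3 lay between 2.24 and 2.57 there, at or near the floor. Granulocytes carried through the sort are a candidate source: 4 of the 12 neutrophil markers on the array exceeded log2 4 there and were higher than on every other array. Camp and Ltf, abundant granule transcripts, stayed at 2.26 and 2.27, and the sort for MHC class II would remove most granulocytes, so the markers leave the question open.

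Differences within the replicate numbers went the same way for 70.2% of the 9350 genes and correlated at 0.60 across genes, which are not independent replicates. Both differences exceeded 1 for 236 genes and both lay below -1 for 146, and 15 genes exceeded 1 in opposite directions. With the numbers crossed the correlation was 0.03.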
